A study of Mus musculus with 6 samples.

How the data were processed

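RNA sequencing was compared between LSK cells of mice given haloperidol (3 libraries) and of mice given DMSO (3 libraries), as the labels name them. Per the labels' protocols, bone was crushed and digested with collagenase, cells were sorted straight into lysis buffer, and cDNA was made with a SMART-Seq kit for low input and turned into libraries with a Nextera kit, which keep no strand, so reads from overlapping antisense genes cannot be told apart. The submitters' processing notes name bcl2fastq 2.19.1.403, TopHat2 2.1.1, HTSeq 0.6.1, DESeq2 1.18.1 and the genome build mm10. The annotation release and the counting options are not given in the sources used here.

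The authors deposited one table of FPKM values, fragments normalized to gene length and sequencing depth, with 38926 genes and 1 column per library, and 0 columns of other samples. Of these, 20633 genes were above 0 in at least 1 library. The values were checked for whole reads. In each library a gene's FPKM values are whole multiples of the worth of 1 read, and with the steps estimated from genes of mean FPKM up to 0.5, whole reads came out for 100.0% of the genes above 0, within 0.001 reads. The libraries' relative scale equalled median-of-ratios size factors of those reads, to within 4.4e-16, so the deposited FPKM were scaled by size factors and not by each library's own total. Gene lengths came out whole for 99.2% of genes, and a common factor of a gene's reads was restored for 404 genes. The total implied by the deposited scale was 0.42% above the recovered total. Recovered reads were used for depth, for the simulated data and for 1 added alternative, while the main test used the FPKM as deposited. Depth was 8821279, 8621595 and 8969053 reads in DMSO replicates 1, 2 and 3, and 8523556, 8743862 and 8871137 reads in haloperidol replicates 1, 2 and 3. Between 11378 and 11529 genes per library reached 1 FPKM. The upper limit of 0 reads was set at 3 counts of the library total. Chi-square per degree of freedom of the recovered reads was 2.92 to 4.75 for pairs of libraries within a group and 12.97 to 18.37 for pairs between groups, so no 2 libraries agreed within sampling noise.

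Each gene with a mean of at least 1 FPKM over the 6 libraries (11436 genes) was tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with a trend in the prior variance, two-sided, no covariate, and Benjamini-Hochberg adjustment at a threshold of 0.05. Adjusted p-values of genes in the text are from this test. Fold changes are on the log2(FPKM + 1) scale and understate the change of low genes. Means and SDs are of FPKM. For 42 gene lists fixed from textbook knowledge, limma's camera test with a preset inter-gene correlation of 0.01 was run on the 40 lists with at least 5 measured genes, and its p-values were adjusted over those lists. None of the 11 lists past that threshold kept its call when the correlation was estimated from the libraries. That setting also refers the statistic to the 4 residual degrees of freedom, so a lost call need not mean correlated genes. For stem cell genes, whose estimated correlation of 0.002 lay below the preset, camera's unadjusted p went from 2.37e-04 to 0.0163. For each list the number of members past the threshold over all genes, and past it with the adjustment made over the list alone, was counted. The median, mean and test direction of a list differed in sign for dopamine receptors and handling (median 0.04, mean -0.14, lower), fatty acid synthesis (median -0.02, mean 0.06, lower), the unfolded protein response (median -0.02, mean 0.03, lower), adhesion (median 0.04, mean -0.04, lower), histone genes (median 0.04, mean -0.04, higher) and the circadian clock (median 0.16, mean -0.01, higher), and the median and mean differed for sex-linked genes (-0.10 and 0.01), which had no list test. The test was tried on simulated reads drawn from the real means and depths for all 11436 genes, 200 of them changed. It recovered 52.0% of the genes changed 1.5-fold and 81.0% of those changed 2-fold and called 10 unchanged genes. With no gene changed it called 0 genes. These reads hold no correlation between genes, so they do not test the list calls. Far fewer genes were changed in them than the 2807 called in the data. Genes of like expression were also given the same spread between replicates. The rates of recovery and of false calls may therefore differ in the real data.

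Groups, lists, the main test, the rule for named genes and the first set of other settings were fixed before the data were examined. Genes named in the text are the 12 with the largest rise and the 12 with the largest fall among genes past the threshold whose groups do not overlap, leaving out predicted genes, clone names, small RNA genes, pseudogene symbols and symbols on more than 1 row. To these were added Lck, Kit, Ly6a, Drd1, Drd2, Drd3, Drd4 and Drd5 whatever their value and, for each list described, up to 4 members with the smallest p, plus the 2 with the largest DMSO mean for a list past its threshold. Some genes that this rule takes are not reported here. Others are said to be chosen after their values were seen. Coordinates are on mm10, from the GENCODE M21 annotation matched by gene symbol, and span the whole gene from its first to its last exon. Some list members are in the table under an older symbol (Drd1a, Sc4mol, Chi3l3, Emr1, Igj, 1100001G20Rik and Gm129), and Hbb-b1, Hbb-b2, Ahsp and Ighd were not analysed here.

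That first set held pseudocounts of 0.1 and 0.01, no filter on low values, a mean of at least 5 FPKM, rescaling each library to a common sum or upper quartile, quantile normalization, no trend or a robust prior in the variance, sample quality weights, the replicate number as a block, each library left out in turn, a threshold of 0.1, an estimated correlation, and fry, a rotation test of whether a list's genes move, on balance, one way. After the data were seen, limma-voom on the recovered reads and the removal of a trend with GC content and length were added, the latter on 11326 genes (99.0% of those tested) that had both. Symbol families were tested with scipy 1.17.1 in Python 3.11.15.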

Results

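RNA was sequenced from mouse LSK cells, the lineage-negative, Sca-1-positive and Kit-positive fraction of bone marrow that holds haematopoietic stem cells and multipotent progenitors. The cells were sorted from digested femur and tibia of C57BL/6 mice injected on 3 consecutive days with haloperidol, an antipsychotic drug that blocks dopamine receptors, or with its solvent DMSO. The drug or the solvent also stayed with the cells during the sort. There were 3 DMSO and 3 haloperidol libraries, and each held between 8523556 and 8969053 reads assigned to genes, as recovered from the steps between low FPKM values. At that depth 0 reads in a library allows up to 0.334 to 0.352 RPM (reads scaled to library size), which covers counting error only. The labels do not say whether the replicates came from separate mice, so the p-values measure the spread between these samples, which may be technical. Neither do they say whether the groups were sorted or sequenced on different days, and a batch that followed the groups cannot be told apart from the treatment. The first principal component held 51.6% of the variance and separated the groups, with DMSO libraries between -17.83 and -16.73 and haloperidol libraries between 14.08 and 20.79. Xist had at most 2 reads in any library, and the Y-linked Ddx3y lay between 18.1 and 24.4 FPKM in all 6 libraries, with means of 21.3 and 20.1 FPKM in DMSO and haloperidol.

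The comparison asked which transcripts differed in LSK cells after haloperidol. Among genes of cholesterol synthesis, inflammatory genes, and genes of stem cells and lymphoid-primed progenitors, more fell than rose with haloperidol, while among glucocorticoid-response genes and ribosomal protein genes more rose than fell. Of 11436 genes tested, 2807 differed at an adjusted p below 0.05, of which 1320 were higher and 1487 lower with haloperidol. Most of these differences were small. A change of at least 2-fold was seen for 70 genes that rose and 79 that fell, and one of at least 4-fold for 3 that rose and 4 that fell. The libraries of the 2 groups did not overlap for 4932 genes (43.1%), where chance gives 10%. Without DMSO replicate 2, 1821 genes differed and 815 were higher, and without haloperidol replicate 1, 869 were higher. With no filter on low values, 848 were higher, and the majority turned with upper quartile scaling (1551 higher and 1327 lower) but not with rescaling to a common sum (1108 and 1559).

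Among the genes that the naming rule allows, the largest rise was that of Pdcd1, which encodes an inhibitory receptor of lymphocytes (chromosome 1, 94038305 to 94052553). It went from 17.1 ± 1.94 FPKM in DMSO to 142 ± 47.9 FPKM in haloperidol (mean ± SD, n = 3 each), a log2 fold change of 2.94 (SE 0.19, adjusted p = 6.12e-05). Cirbp, the cold-inducible RNA-binding protein (chromosome 10, 80165985 to 80172786), rose from 47.1 ± 2.52 to 143 ± 8.05 FPKM, a log2 fold change of 1.58 (SE 0.06, adjusted p = 5.53e-06). The metallothionein genes Mt1 and Mt2, which bind metals, rose from 24 ± 4.72 to 107 ± 39.8 and from 4.73 ± 1.31 to 15.2 ± 3.15 FPKM. Hvcn1, a voltage-gated proton channel, rose from 8.99 ± 1.22 to 37.7 ± 7.02 FPKM. Among genes of myeloid cells, the macrophage glycoprotein gene Cd68 rose from 16.2 ± 0.987 to 44.9 ± 3.90 FPKM, the chemokine gene Ccl9 from 35.3 ± 1.30 to 97.1 ± 16.2 FPKM, and Ms4a3, a gene of granulocyte and monocyte progenitors, from 4.76 ± 0.480 to 15.0 ± 4.73 FPKM. The other 4 of the 12 largest rises under that rule were those of Fam181b (log2 fold change 1.54, SE 0.20), the helicase-family gene Dhx40 (1.48, SE 0.08), the sulfotransferase gene Sult1a1 (1.47, SE 0.26) and Rab44. This last, a small GTPase gene, rose from 5.03 ± 0.763 to 14.9 ± 1.45 FPKM. Adjusted p for these 12 genes was at most 0.00501.

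Cd83, a surface protein of activated dendritic cells and lymphocytes (chromosome 13, 43784775 to 43803132), fell from 562 ± 22.9 to 129 ± 25.2 FPKM (n = 3 each), a log2 fold change of -2.13 (SE 0.12, adjusted p = 3.21e-05). Ltb, which encodes the cytokine lymphotoxin beta (chromosome 17, 35194439 to 35196320), fell from 91.7 ± 6.55 to 21.5 ± 0.251 FPKM, a log2 fold change of -2.04 (SE 0.06, adjusted p = 2.34e-06). Ly6d, a marker of early B lineage progenitors, fell from 11 ± 1.23 to 2.2 ± 0.355 FPKM, and the syndecan gene Sdc1 from 13.5 ± 0.945 to 3.73 ± 0.674 FPKM. Areg, a ligand of the epidermal growth factor receptor, fell from 42.7 ± 2.98 to 11.1 ± 1.08 FPKM. Gfi1b, a transcriptional repressor needed for erythroid and megakaryocytic cells, fell from 17.3 ± 1.37 to 4.84 ± 0.270 FPKM. The germ cell helicase gene Ddx4 (log2 fold change -1.79, SE 0.16) and the chemokine gene Ccl3 (-1.52, SE 0.18) were also among the 12 largest falls under the naming rule. Another 3 are antigen receptor gene segments with few reads, which share sequence with related segments and are uncertain. Ighd4-1 had 4 to 16 reads in the DMSO libraries and at most 2 in the haloperidol libraries, Ighv1-62-1 had 5 to 7 and at most 2, and Trbv4 had 4 to 9 and at most 1. Their log2 fold changes were set by the pseudocount, being -4.43, -2.48 and -1.56 with a pseudocount of 1 and -8.86, -6.89 and -6.09 with 0.01, and the call for Ighd4-1 ended with a robust prior variance (adjusted p = 0.0765). Adjusted p for these 11 genes was at most 0.00878.

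**Figure D1:**
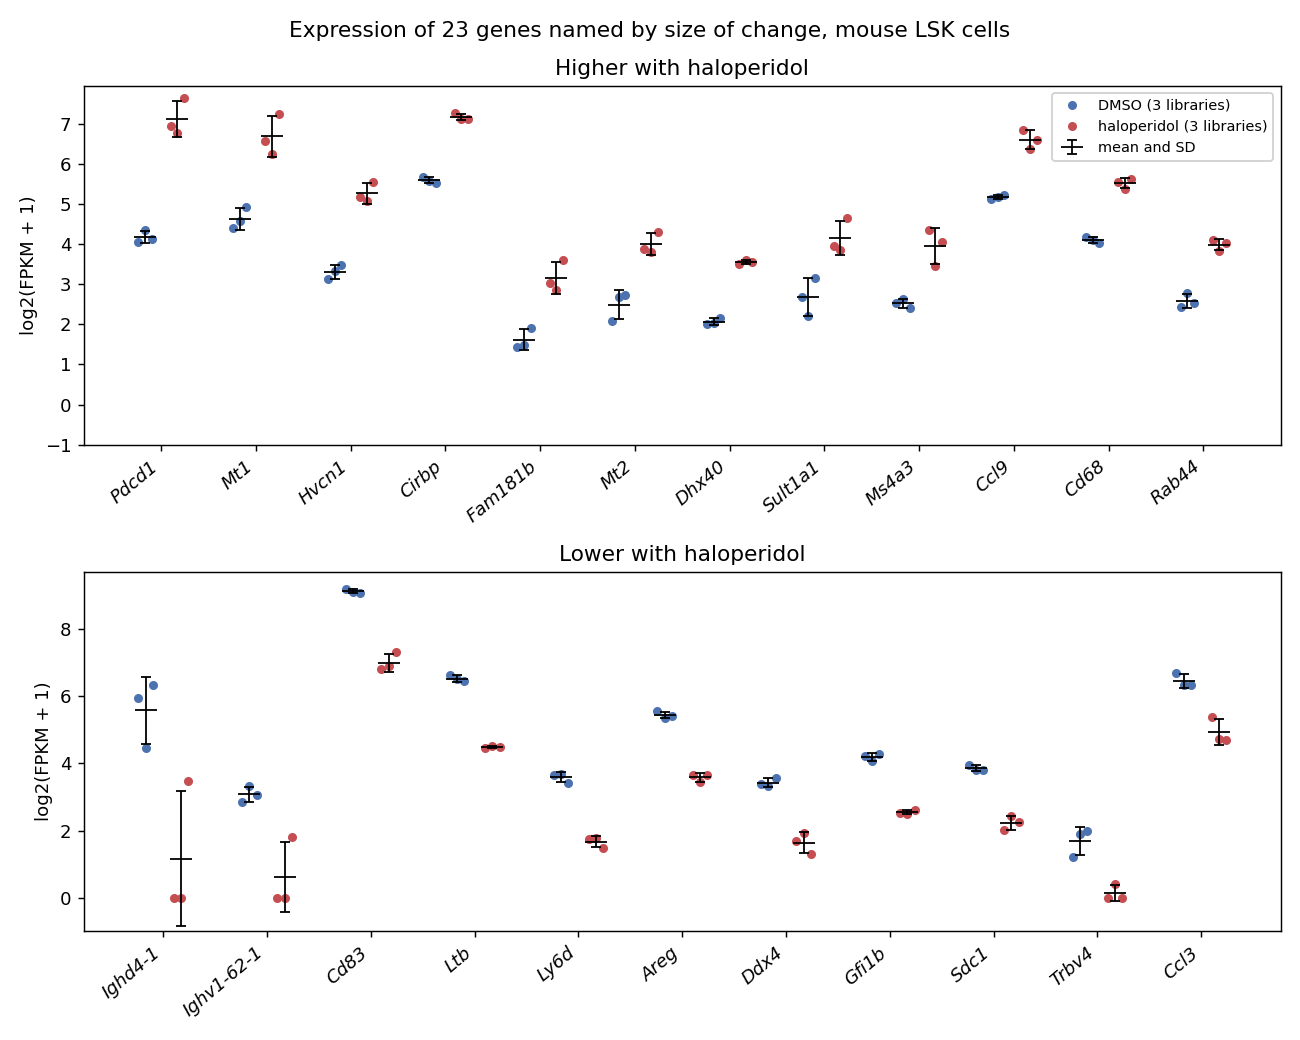
Expression of the 12 genes with the largest rise (upper panel) and of 11 of the 12 with the largest fall (lower panel), among genes that the naming rule allows. The vertical axis is log2(FPKM + 1) for each of the 3 DMSO and 3 haloperidol libraries, with the mean and SD of each group as a bar and whiskers. For each gene all 3 libraries of one group lie on one side of the 3 of the other, and Pdcd1 goes from a mean of 17.1 FPKM in DMSO to 142 FPKM in haloperidol.

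Among the genes chosen in advance, Lck, a Src family kinase of lymphocytes and progenitors (chromosome 4, 129548344 to 129573641), fell from 25.8 ± 0.827 to 17.7 ± 0.825 FPKM (n = 3 each), a log2 fold change of -0.53 (SE 0.06, adjusted p = 6.75e-04). The genes of the surface proteins Kit and Sca-1, which define the gate, did not pass the test. The cells were sorted on both proteins, so the gate itself may limit differences in these genes. Kit was at 87.8 ± 7.38 and 81.0 ± 9.78 FPKM (adjusted p = 0.396), and Ly6a, which encodes Sca-1, at 136 ± 10.2 and 138 ± 10.5 FPKM (adjusted p = 0.861). The dopamine receptor genes Drd2, Drd3 and Drd5 had 0 reads in all 6 libraries. Drd1 (listed as Drd1a) had 1 read in one DMSO library and Drd4 had 1 read in one haloperidol library. Expression of these receptors was not detectable at this depth. Of the 6 measured genes of dopamine receptors and handling, 2 fell (2 adjusted over the list alone, with 1 higher), and 1 also rose with upper quartile scaling or quantile normalization. Among them the vesicular transporter gene Slc18a1 fell from 2.93 ± 0.444 to 1.15 ± 0.249 FPKM. Of 3 measured catecholamine and serotonin receptor genes, 2 fell (2 adjusted over the list alone).

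Most measured genes of cholesterol biosynthesis and other SREBP2 targets fell. Of 24 on that list, 14 fell and 0 rose (17 and 0 adjusted over the list alone), and 10 did not pass. Srebf2, which encodes the SREBP2 transcription factor, fell from 58.9 ± 0.311 to 37.1 ± 1.84 FPKM. Fdps, an enzyme of the mevalonate pathway, fell from 39.2 ± 1.90 to 23.8 ± 1.02 FPKM, and Insig1, a sterol-regulated brake on SREBP processing, from 28.7 ± 0.637 to 11.4 ± 1.98 FPKM. The list test, camera with a preset correlation, gave adjusted p = 5.32e-09. The call was lost at adjusted p = 0.32 with an estimated correlation.

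Of 17 measured NF-kB and inflammatory genes, 14 fell and 1 rose (14 and 1 adjusted over the list alone). Nfkbiz, a nuclear regulator induced by NF-kB, fell from 168 ± 8.50 to 79.2 ± 5.53 FPKM, Tnfaip2 from 22.2 ± 0.116 to 11.5 ± 0.17 FPKM, and the adhesion molecule gene Icam1 from 163 ± 8.10 to 93.1 ± 10.7 FPKM. The chemokine genes Ccl3 and Ccl4 fell from 87.4 ± 13.5 to 30.4 ± 9.0 and from 588 ± 48.5 to 444 ± 50.8 FPKM, though the call for Ccl4 ended with no filter on low values (adjusted p = 0.058), and the NF-kB inhibitor gene Nfkbia fell from 1049 ± 9.92 to 681 ± 94.0 FPKM. In the list test the adjusted p was 4.27e-06. It became adjusted p = 0.356 with an estimated correlation. Of 28 measured interferon response genes, 10 fell and 0 rose (10 and 0 adjusted over the list alone). They included Isg15, a ubiquitin-like protein, from 48.7 ± 1.48 to 33.3 ± 1.69 FPKM, and the transcription factor gene Irf1, from 112 ± 0.935 to 91.9 ± 4.47 FPKM. Oasl2 fell with a log2 fold change of -0.46 (SE 0.07), while Bst2, one of the most abundant members, was at 116 ± 3.53 and 116 ± 12.2 FPKM. As a list these genes had adjusted p = 0.0362. The test gave adjusted p = 0.356 with an estimated correlation. That call also ended with sample quality weights (adjusted p = 0.0549), without DMSO replicate 1 (adjusted p = 0.0896) and without haloperidol replicate 3 (adjusted p = 0.0554).

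Glucocorticoid-response genes mostly rose. Of 15 measured, 9 rose and 2 fell (11 and 2 adjusted over the list alone). Fkbp5, a co-chaperone of the glucocorticoid receptor (chromosome 17, 28399094 to 28517527), rose from 11.7 ± 0.830 to 31.6 ± 1.11 FPKM, a log2 fold change of 1.36 (SE 0.07, adjusted p = 2.15e-05). Tsc22d3, which encodes the glucocorticoid-induced leucine zipper protein, rose from 79.0 ± 15.1 to 196 ± 6.58 FPKM, and the transcription factor gene Klf9 from 16.6 ± 2.09 to 34.3 ± 3.34 FPKM. The phosphatase gene Dusp1 went the other way, from 287 ± 8.61 to 210 ± 8.79 FPKM, and the cell cycle inhibitor gene Cdkn1a, the most abundant member, was at 443 ± 28.9 and 483 ± 64.6 FPKM (adjusted p = 0.39). The list test gave adjusted p = 9.58e-05. The call was lost at adjusted p = 0.32 with an estimated correlation.

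Among genes of stem cells and of lymphoid-primed progenitors, more fell than rose. Of 26 measured haematopoietic stem cell genes, 11 fell and 2 rose (13 and 2 adjusted over the list alone). Esam, an adhesion molecule of stem cells and endothelium (chromosome 9, 37528078 to 37538319), fell from 24.9 ± 1.21 to 13.0 ± 1.76 FPKM. The transcription factor genes Meis1 and Hlf fell from 27.7 ± 0.897 to 18.8 ± 1.28 and from 30.6 ± 4.08 to 14.5 ± 2.36 FPKM. Ifitm1 rose from 382 ± 22.6 to 598 ± 51.1 FPKM, and Ifitm3 was at 597 ± 18.8 and 625 ± 45.5 FPKM (adjusted p = 0.486). Cd34, a surface sialomucin of progenitors, fell from 648 ± 24.7 to 557 ± 19.4 FPKM, a call that ended without DMSO replicate 2 (adjusted p = 0.066) and with no filter on low values (adjusted p = 0.0598). In the list test the adjusted p was 0.00118. It became adjusted p = 0.32 with an estimated correlation. Of 17 measured genes of multipotent and lymphoid-primed progenitors, 11 fell and 2 rose (11 and 3 adjusted over the list alone), or 11 and 1 with rescaling to a common sum. The chromatin organiser gene Satb1 fell from 19.8 ± 0.935 to 10.5 ± 0.841 FPKM, Cd27, a receptor of the tumour necrosis factor receptor family, from 114 ± 0.596 to 78.6 ± 4.20 FPKM, and Rag2, part of the recombinase of antigen receptor genes (chromosome 2, 101624718 to 101632529), from 2.36 ± 0.381 to 0.177 ± 0.0825 FPKM. Il12a fell from 20.1 ± 2.65 to 9.30 ± 1.14 FPKM, and Dntt, the terminal transferase of lymphoid progenitors, from 337 ± 32.4 to 194 ± 29.1 FPKM. As a list these genes had adjusted p = 3.32e-04. The test gave adjusted p = 0.356 with an estimated correlation. Of 9 measured endothelial markers, 3 fell and 0 rose (3 and 0 adjusted over the list alone), and the list did not pass its test (adjusted p = 0.187). Tie1, which is on both lists, was at 14.5 ± 1.07 and 10.1 ± 0.786 FPKM and Eng at 21.6 ± 1.46 and 16.1 ± 0.969 FPKM.

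Most genes on the list of B cell and plasma cell markers fell, but Igkc and Jchain did not. Of 9 measured, 7 fell and 0 rose (7 and 1 adjusted over the list alone). Ighm, the heavy chain gene of immunoglobulin M (chromosome 12, 113418558 to 113422730), fell from 262 ± 18.7 to 102 ± 12.3 FPKM, a log2 fold change of -1.36 (SE 0.09, adjusted p = 5.73e-05). Cd79b, a signalling chain of the B cell receptor, fell from 32.2 ± 1.12 to 22.8 ± 1.24 FPKM, and the adaptor gene Blnk from 1.62 ± 0.0934 to 0.506 ± 0.0867 FPKM. The light chain gene Igkc, singled out after its values were seen, was at 23.9 ± 23.1 and 84.4 ± 60.0 FPKM (adjusted p = 0.107 over all genes). Jchain (listed as Igj), also singled out afterwards, had means of 2.92 FPKM in DMSO and 3.93 FPKM in haloperidol. DMSO replicate 2 had 4 reads of Igkc and 2 of Jchain but 433 of Sdc1. The list test gave adjusted p = 3.03e-04. The call was lost at adjusted p = 0.356 with an estimated correlation. Of 13 measured T cell and NK cell markers, 2 fell and 0 rose (2 and 0 adjusted over the list alone). The transcription factor gene Tcf7 fell from 2.56 ± 0.423 to 0.963 ± 0.380 FPKM, and Cd5 from 1.56 ± 0.257 to 0.641 ± 0.0869 FPKM (list test adjusted p = 0.155). Of 11 measured markers of monocytes, macrophages and dendritic cells, 5 fell and 1 rose (5 and 1 adjusted over the list alone), with a list test adjusted p = 0.169. The antigen presentation genes Cd74, H2-Aa and H2-Ab1 fell from 148 ± 19.2 to 73.0 ± 1.04, from 25.1 ± 2.22 to 11.2 ± 1.83 and from 74.9 ± 8.01 to 52.1 ± 3.24 FPKM, while Cd68 rose. Immunoglobulin and H2 genes share reads with related genes and their levels are uncertain.

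Lineage genes of myeloid and erythroid progenitors moved in both directions. Of 17 measured myeloid progenitor genes, 7 rose and 4 fell (8 and 4 adjusted over the list alone, list test adjusted p = 0.169). The granule protease genes Prtn3 and Ctsg rose from 117 ± 6.57 to 198 ± 16.9 and from 78.7 ± 6.94 to 192 ± 37.9 FPKM. The transcription factor genes Irf8 and Spi1 fell from 13.0 ± 0.255 to 6.89 ± 0.907 and from 144 ± 5.41 to 102 ± 7.48 FPKM. Of 19 measured megakaryocyte and erythroid progenitor genes, 2 rose and 6 fell (3 and 8 adjusted over the list alone, list test adjusted p = 0.169). The platelet integrin gene Itga2b rose from 18.7 ± 1.13 to 44.8 ± 4.06 FPKM. The carbonic anhydrase gene Car2 fell from 843 ± 29.5 to 561 ± 25.2 FPKM and the erythroid transcription factor gene Klf1 from 10.2 ± 2.97 to 4.57 ± 0.554 FPKM. Of 5 measured mast cell and basophil markers, 3 rose and 1 fell (3 and 1 adjusted over the list alone, list test adjusted p = 0.153). The protease genes Cpa3 and Mcpt8 rose from 34.8 ± 3.01 to 61.1 ± 6.44 and from 7.57 ± 1.91 to 18.7 ± 2.40 FPKM. Of 14 measured neutrophil markers, 3 rose and 1 fell (3 and 1 adjusted over the list alone, list test adjusted p = 0.244). The lysozyme gene Lyz2 fell from 391 ± 25.2 to 266 ± 18.4 FPKM and Ifitm6 rose from 1.4 ± 0.634 to 4.14 ± 1.06 FPKM. Transcripts of mature erythroid cells were abundant in both groups and 0 of 9 measured passed the test (0 adjusted over the list alone, list test adjusted p = 0.671), while 1 rose with upper quartile scaling or quantile normalization. Hbb-bs, a beta globin gene, was at 1489 ± 188 FPKM in DMSO and 1904 ± 265 FPKM in haloperidol (adjusted p = 0.0589). Of 7 measured stromal and osteolineage markers, 1 rose (1 adjusted over the list alone, list test adjusted p = 0.187). Of 4 measured sex-linked genes 0 passed (0 adjusted over the list alone), while 1 rose with upper quartile scaling or quantile normalization.

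Part of the genes of mitosis fell, and part of the ribosomal protein genes rose. Of 24 measured G2 and M phase genes, 10 fell and 0 rose (14 and 0 adjusted over the list alone). The mitotic kinase genes Aurka and Plk1 fell from 25.4 ± 1.92 to 14.8 ± 1.42 and from 21.9 ± 2.78 to 11.6 ± 1.19 FPKM. The kinesin gene Kif23 fell from 29.1 ± 0.636 to 19.1 ± 0.781 FPKM, Hmmr from 12.5 ± 1.39 to 7.64 ± 0.224 FPKM, and Cdc20, an activator of the anaphase-promoting complex, from 62.7 ± 5.04 to 45.0 ± 1.56 FPKM. The cyclin gene Ccnb2 was at 86.7 ± 8.72 and 93.9 ± 4.93 FPKM (adjusted p = 0.305). In the list test the adjusted p was 2.89e-04. It became adjusted p = 0.551 with an estimated correlation. Of 24 measured S phase genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone, list test adjusted p = 0.283), or 4 and 2 with upper quartile scaling. The replication licensing gene Cdt1 rose from 36.9 ± 1.71 to 57.6 ± 3.71 FPKM. Of 32 measured cytosolic ribosomal protein genes, 16 rose and 0 fell (23 and 0 adjusted over the list alone). Rpl27 rose from 172 ± 10.2 to 226 ± 10.9 FPKM, Rps2 from 65.1 ± 5.92 to 86.4 ± 5.24 FPKM, Rpl8 from 660 ± 35.5 to 803 ± 35.3 FPKM and Rpl30 from 58.0 ± 3.62 to 71.0 ± 2.70 FPKM. The 2 members most abundant in DMSO, Rpl32 and Rpl4, were at 2085 ± 125 and 2255 ± 126 FPKM (adjusted p = 0.234) and at 1078 ± 10.4 and 1085 ± 10.9 FPKM (adjusted p = 0.899). Ribosomal protein genes share reads with their pseudogenes and their levels are uncertain. As a list these genes had adjusted p = 6.75e-06. The test gave adjusted p = 0.551 with an estimated correlation. With fry the ribosomal protein call also ended (adjusted p = 0.0505). For the ribosomal protein list and the G2 and M phase list alike, 3 of the 10 splits of the libraries into 3 and 3, the real one included, gave a camera p as small.

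Of 22 measured MYC target and ribosome biogenesis genes, 7 rose and 2 fell (9 and 2 adjusted over the list alone), or 7 and 1 with quantile normalization. Myc itself rose from 103 ± 3.49 to 143 ± 2.87 FPKM, the nucleolar methyltransferase gene Fbl from 153 ± 3.05 to 177 ± 1.06 FPKM, Bop1 from 57.4 ± 1.61 to 69.4 ± 4.14 FPKM and the nucleophosmin gene Npm1 from 247 ± 4.30 to 284 ± 6.31 FPKM. Odc1, an enzyme of polyamine synthesis, fell from 247 ± 16.7 to 210 ± 10.3 FPKM, and its call ended without DMSO replicate 1 or 2 or haloperidol replicate 1 or 2 (adjusted p = 0.0789, 0.0683, 0.0916 and 0.052). The list test gave adjusted p = 0.042. The call was lost at adjusted p = 0.54 with an estimated correlation. Of 28 measured nuclear-encoded oxidative phosphorylation genes, 5 rose and 0 fell (2 and 0 adjusted over the list alone), and with rescaling to a common sum or quantile normalization 4 rose and 1 fell. The complex I gene Ndufv1 rose from 82.0 ± 2.21 to 97.7 ± 4.43 FPKM, while the members most abundant in DMSO, Ndufa4 and Atp5b, were at 841 ± 37.2 and 855 ± 29.4 FPKM and at 519 ± 13.3 and 540 ± 14.8 FPKM. In the list test the adjusted p was 0.0464. It became adjusted p = 0.65 with an estimated correlation. Leaving out 1 library also ended both calls, at adjusted p = 0.0896, 0.0535, 0.0787 and 0.0554 for the MYC list without DMSO replicate 1, DMSO replicate 2, haloperidol replicate 2 and haloperidol replicate 3, and at adjusted p = 0.146 and 0.169 for the oxidative phosphorylation list without DMSO replicate 1 and haloperidol replicate 3. Both calls also ended with rescaling to a common sum (adjusted p = 0.0632 each) and with quantile normalization (0.0547 and 0.158). The oxidative phosphorylation call ended as well with sample quality weights (adjusted p = 0.0984) and with the replicate number as a block (adjusted p = 0.0519). Of 14 measured mitochondrially encoded genes, 1 rose (1 adjusted over the list alone, list test adjusted p = 0.0915), which was mt-Nd1, from 465 ± 34.4 to 641 ± 59.0 FPKM.

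**Figure D2:**
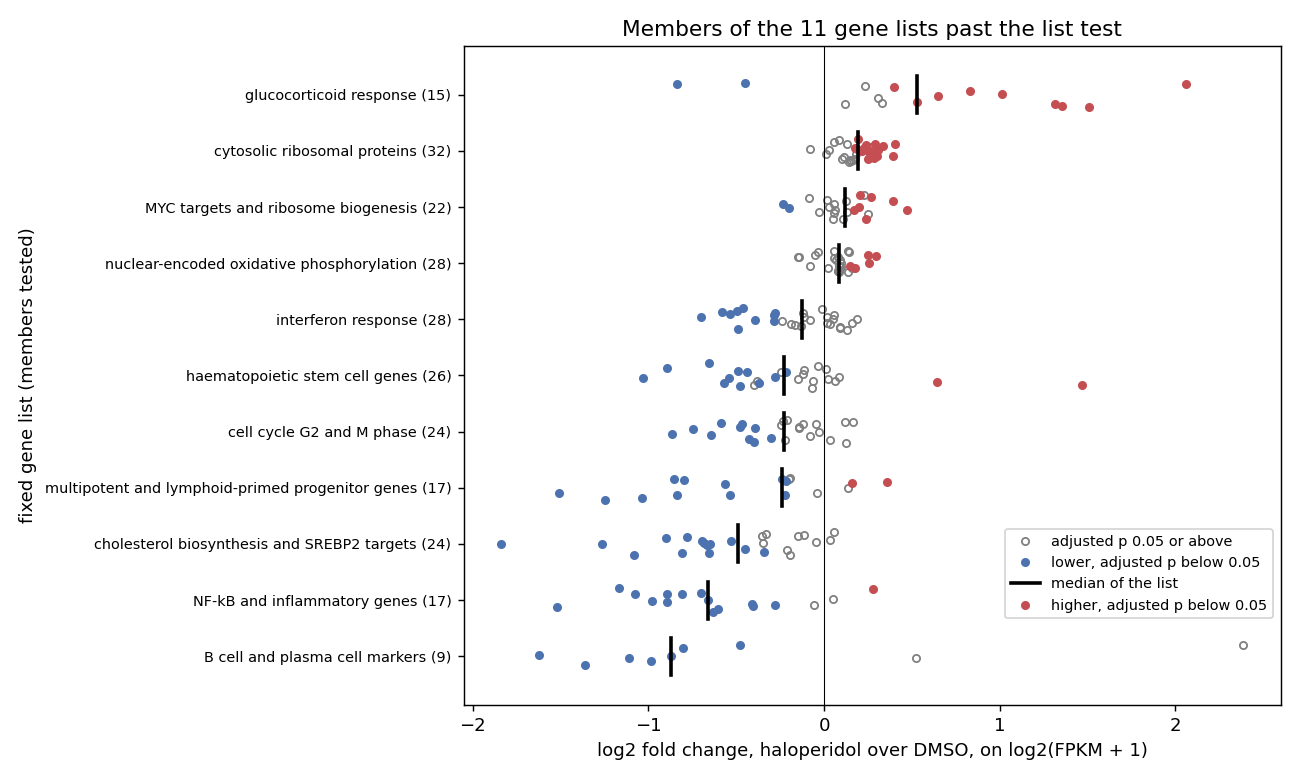
Log2 fold change of haloperidol over DMSO on log2(FPKM + 1) (horizontal axis) for each measured member of the 11 gene lists past the list test (rows, with the number of members measured), filled where the gene's adjusted p was below 0.05 and with the list's median as a black bar. Medians run from -0.87 for B cell and plasma cell markers to 0.53 for glucocorticoid-response genes.

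Signalling genes changed in part. Of 10 measured Src family and proximal T cell receptor signalling genes, 3 fell and 0 rose (3 and 0 adjusted over the list alone, list test adjusted p = 0.11). These were Lck, the adaptor gene Lcp2, from 36.0 ± 1.27 to 22.1 ± 1.81 FPKM, and the kinase gene Fyn, from 28.4 ± 1.08 to 22.8 ± 0.995 FPKM. Of 23 measured components of KIT, FLT3 and related cytokine receptor signalling, 3 rose and 7 fell (4 and 7 adjusted over the list alone, list test adjusted p = 0.242), or 1 and 6 with rescaling to a common sum. The phosphoinositide kinase gene Pik3cd fell from 23.3 ± 2.21 to 16.1 ± 1.69 FPKM. Of 15 measured ERK output and feedback genes, 1 rose and 7 fell (1 and 8 adjusted over the list alone, list test adjusted p = 0.0688). Myc was the gene that rose, and the phosphatase gene Dusp6 fell from 91.1 ± 2.25 to 66.7 ± 3.24 FPKM and Phlda1 from 58.0 ± 5.10 to 30.9 ± 6.15 FPKM. Of 17 measured cAMP and CREB target genes, 3 rose and 6 fell (3 and 6 adjusted over the list alone, list test adjusted p = 0.409). Areg, the cyclooxygenase gene Ptgs2 (174 ± 11.5 to 65.7 ± 3.17 FPKM), Gem (131 ± 5.05 to 76.1 ± 2.29 FPKM) and the nuclear receptor gene Nr4a2 (441 ± 16.0 to 296 ± 19.2 FPKM) fell. Of 19 measured immediate early genes, 3 rose and 10 fell (3 and 10 adjusted over the list alone, list test adjusted p = 0.0915). Junb fell from 2030 ± 52.2 to 1526 ± 74.4 FPKM, and Klf6 and Atf3 rose from 29.3 ± 1.68 to 48.3 ± 3.14 and from 80.7 ± 2.69 to 114 ± 6.74 FPKM. Of 14 measured heat shock genes, 6 fell and 0 rose (6 and 0 adjusted over the list alone, list test adjusted p = 0.06). The chaperone genes Hsph1 and Hspa8 fell from 21.2 ± 3.78 to 7.85 ± 0.431 and from 569 ± 15.6 to 450 ± 5.74 FPKM.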

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

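Limma-voom on the recovered reads and the removal of a GC content and length trend were chosen after the results were seen. The 2807 genes became 3330 and 2962 with them, 2667 to 2878 with other scalings (1108 higher and 1559 lower with a common sum, 1551 and 1327 with the upper quartile), and 1954 with no filter on low values, which tests 20633 genes. With no filter 848 genes were higher in place of 1320. With 1 library left out, 1821 to 2148 genes differed, 815 to 957 of them higher, as fewer samples were tested. The 11 lists became 0 with an estimated correlation, a setting that also rests on the 4 residual degrees of freedom. They became 23 with fry, which does not compare a list with other genes, and 8 to 14 with 1 library left out. No call of a named gene or list turned its direction under these settings. Of 131 called named genes, 125 kept their call in each setting that tested them, and Ighd4-1, Ccl4, Cd34, Flt3, Odc1 and Smap2 lost it in 30 values. A mean of at least 5 FPKM left only 119 of the 131 genes and 10 of the 11 lists to test. The 11 list calls were lost in 28 values, 11 of them with the estimated correlation. Rescaling to a common sum and quantile normalization each ended the calls for MYC targets (adjusted p = 0.0632 and 0.0547) and oxidative phosphorylation (0.0632 and 0.158), and fry those for ribosomal proteins (0.0505) and oxidative phosphorylation (0.0975). Equal replicate numbers did not pair the samples: correlations of their deviations were 0.009, 0.055 and 0.020, and 1 of the 3 numbers matched its own best. With the replicate number as a block, 2552 genes and 10 lists passed, and the calls for Flt3, Odc1 and the oxidative phosphorylation list ended. Among genes that did not pass, the log2 fold change turned with quantile normalization for Ly6a (-0.00), Atp5b (-0.02), Ifitm3 (-0.01), Ndufa4 (-0.06) and Rpl4 (-0.06), with a common sum for Rpl4 (-0.01), with the upper quartile for Bst2 (0.02), and without the GC and length trend for Ly6a (-0.01) and Ndufa4 (-0.04). With 1 library left out it ran from -0.04 to 0.08 for Ly6a, from -0.10 to 0.03 for Bst2, from -0.19 to 0.02 for Ddx3y and from -0.01 to 0.05 for Ndufa4. The direction of a list that did not pass turned with a mean of at least 5 FPKM for dopamine handling (adjusted p = 0.818) and adhesion (0.808), without the GC and length trend for adhesion (0.942), with fry for histone genes (0.113) and the circadian clock (0.51), and with 1 library left out for the unfolded protein response (0.543 to 0.978) and mature erythroid markers (0.363 to 0.954). Apart from fewer samples or other genes tested, the cause was not tested. Genes of few reads, such as the antigen receptor segments, are limited by depth.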

Other observations

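Of the tests in this part, those of symbol families, of the response to handling, of Igkc, of the GC content and length trend and the splits of the samples were chosen only after the results were seen. The 2 further gene lists were drawn up after the patterns they test were seen and before the values of their members were. Of the symbol families tested, 4 held more calls in one direction than other genes did (496 one-sided Fisher's exact tests over families of at least 6 measured genes, per direction). Of 8 measured Gimap genes, which encode GTPases of lymphocyte survival, 6 fell (adjusted p = 0.0137, median log2 fold change -0.65), with Gimap1 going from 74.0 ± 3.15 to 41.3 ± 0.439 FPKM and Gimap6 from 96.0 ± 4.18 to 54.9 ± 3.30 FPKM (n = 3 each). Of 6 measured Zkscan zinc finger genes, 5 rose (adjusted p = 0.0137, median 0.35), though with rescaling to a common sum 2 rose, and Zkscan14 went from 24.3 ± 0.667 to 31.7 ± 2.03 FPKM. Of 47 genes with the stem Rpl, 25 rose and 1 fell (adjusted p = 1.71e-09 for the rise), and of 42 with the stem Rps, which includes ribosomal kinases, 18 rose and 2 fell (adjusted p = 6.80e-05). Fisher's test takes genes as independent, and the fixed list of ribosomal proteins, whose estimated correlation was 0.706, had adjusted p = 0.551 with that correlation and a p as small in 3 of the 10 splits of the samples.

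Several metabolic and stress lists held genes that moved both ways and did not pass the list test. Of 23 measured glycolysis and hypoxia genes, 9 rose and 3 fell (9 and 4 adjusted over the list alone, list test adjusted p = 0.169). The prolyl hydroxylase gene Egln3 fell from 57.3 ± 3.04 to 33.4 ± 0.724 FPKM and Vegfa from 59.1 ± 5.54 to 31.8 ± 3.77 FPKM, while Pdk1 rose from 19.8 ± 0.823 to 30.3 ± 0.911 FPKM and Gapdh, which shares reads with many pseudogenes and is uncertain, from 16.4 ± 0.490 to 26.1 ± 1.20 FPKM. Of 12 measured circadian clock genes, 2 rose and 3 fell (2 and 3 adjusted over the list alone, list test adjusted p = 0.647), with Arntl falling from 7.12 ± 0.782 to 3.84 ± 0.214 FPKM and Dbp from 4.57 ± 0.315 to 2.58 ± 0.116 FPKM. The counts of genes that rose and fell were 3 and 1 of 17 for oxidative stress and NRF2 targets (3 and 1 adjusted over the list alone, list test adjusted p = 0.187), led by the rise of Gsr from 48.2 ± 2.32 to 72.2 ± 4.24 FPKM. They were 3 and 3 of 18 for the unfolded protein response (3 and 3 adjusted over the list alone, list test adjusted p = 0.86), led by the rise of Asns from 10.4 ± 1.81 to 19.8 ± 0.924 FPKM. They were 2 and 3 of 12 for fatty acid synthesis (2 and 3 adjusted over the list alone, list test adjusted p = 0.717), led by the rise of Scd1 from 0.516 ± 0.258 to 2.93 ± 1.0 FPKM, and 2 and 3 of 16 for histone genes and chromatin (4 and 3 adjusted over the list alone, list test adjusted p = 0.805), led by the fall of Hist1h2ae from 10.2 ± 1.13 to 4.42 ± 0.648 FPKM. They were 1 and 5 of 17 for apoptosis regulators (1 and 7 adjusted over the list alone, list test adjusted p = 0.187), with Bcl2l11 rising from 48.3 ± 1.72 to 63.6 ± 4.11 FPKM, and 0 and 2 of 13 for p53 targets (0 and 2 adjusted over the list alone, list test adjusted p = 0.366), led by Gtse1. They were 1 and 4 of 16 for cell cycle inhibitors (2 and 4 adjusted over the list alone, list test adjusted p = 0.263), led by the fall of Btg2, 3 and 4 of 19 for adhesion and niche retention (3 and 5 adjusted over the list alone, list test adjusted p = 0.805), led by the fall of Esam, and 1 and 3 of 24 for lysosome genes (1 and 2 adjusted over the list alone, list test adjusted p = 0.465), led by the rise of Ctsz. Some of these counts moved with the scaling. With upper quartile scaling 5 histone genes rose and 3 fell, which turns the majority, and with a common sum or quantile normalization 3 rose and 3 fell. With upper quartile scaling the counts were 5 and 0 for oxidative stress, 2 and 2 for lysosome genes and 2 and 3 for cell cycle inhibitors. With a common sum they were 7 and 3 for glycolysis and hypoxia and 2 and 1 for oxidative stress. With quantile normalization they were 3 and 0 for oxidative stress, 1 and 3 for fatty acid synthesis, 2 and 3 for lysosome genes and 2 and 4 for cell cycle inhibitors.

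The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 2807 genes and the highest of the other splits 1, and 1 of the 10 splits gave as many genes. The real split called 11 lists with the preset correlation and the others 4 to 10, and 1 of the 10 gave as many lists. The smallest p of each list over the 10 splits was that of the real split for cholesterol biosynthesis, NF-kB, glucocorticoid response, stem cell, lymphoid-primed and B cell genes among the lists past the threshold. For the others, 2 (interferon response, MYC targets), 3 (G2 and M phase, ribosomal proteins) or 5 (oxidative phosphorylation) of the splits, the real one included, gave a p as small.

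Of the measured genes, 9 of 15 on the glucocorticoid-response list rose and 14 of 17 on the NF-kB list fell, and a candidate explanation is more glucocorticoid signalling in the treated mice, tested on 12 further glucocorticoid-induced genes that are not on the fixed list. Of these, 6 rose (Cebpd, Arrdc2, Bcl6, Zfp36l2, Map3k6 and Irs2) while Smap2 was called lower, a call that ended without DMSO replicate 1 or 2 (adjusted p = 0.0939 and 0.0743) or haloperidol replicate 2 or 3 (0.0912 and 0.0889). Their median log2 fold change of 0.39 was at percentile 100 of 10000 expression-matched random lists (5th to 95th percentile -0.12 to 0.14), the direction that explanation predicts. But such lists leave out that these genes move together. Limma's camera test gave p = 1.16e-04 with the preset correlation and p = 0.0988 with their estimated correlation of 0.236. The latter setting also rests on the 4 residual degrees of freedom. More glucocorticoid signalling therefore stays open. A weaker response to handling of the cells would lower immediate early genes about as much as NF-kB genes. The immediate early list had a median of -0.23, with 3 rising and 10 falling, against -0.66 for the NF-kB list. Its list test gave adjusted p = 0.0915, with a p as small in 3 of the 10 splits. The labels do not say whether the groups were handled alike, so such a response cannot be told apart from the treatment. Whether the hormone, the drug itself or its presence during the sort lies behind the pattern was not tested.

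Cold-inducible Cirbp rose, as did Rbm3, another cold-induced gene singled out after its values were seen (52.7 ± 3.89 to 88.4 ± 2.98 FPKM), while 6 of 14 heat shock genes fell, 8 did not pass, and the list did not pass its test (adjusted p = 0.06, adjusted p = 0.557 with an estimated correlation, and a p as small in 4 of the 10 splits of the samples). A candidate explanation is a lower temperature, of the mice or of the cells in handling. Of 12 further targets of the heat shock factor HSF1 that are not on the fixed list, 6 fell, led by Ppid, Ahsa1, Fkbp4 and Stip1, and 0 rose. Their median log2 fold change of -0.19 was at percentile 0.2 of 10000 matched random lists (5th to 95th percentile -0.08 to 0.14), and 1 of the 10 splits gave a median as far from 0, the highest of the others being 0.13. This is the direction a lower temperature predicts, but random lists leave out that these genes move together. Limma's camera test gave p = 0.0223 with the preset correlation and p = 0.244 with their estimated correlation of 0.192. The latter setting also rests on the 4 residual degrees of freedom. A lower temperature of mice or cells and the drug as a direct cause therefore stay open.

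Ighm, the antigen presentation genes Cd74, H2-Aa and H2-Ab1 and the lymphoid genes Ltb, Ly6d, Satb1, Rag2 and Dntt were lower with haloperidol. Fewer mature B or plasma cells among the sorted haloperidol cells would lower the abundant light chain transcript Igkc with Ighm. The sort was on lineage-negative cells, but how many mature B or plasma cells remained after it was not measured. The log2 fold change of Igkc lay 3.75 (SE 0.97) above that of Ighm, and 2.54 (SE 0.51) above it without DMSO replicate 2, where Igkc had 4 reads and without which its own log2 fold change went from 2.39 to 1.12, and this argues against such cells as the source of the fall in Ighm. Removing a trend with GC content and length left the median of these genes and H2-Eb1, 10 in all, at -1.15, from -1.15 before, which argues against such a trend. Fewer B lineage progenitors without light chain transcripts, a change in the make-up of the LSK gate and lower expression per cell stay open and were not tested. On the B cell marker list, Vpreb1, Vpreb3 and Igll1, singled out after their values were seen, had few reads. They had 16 to 33, 10 to 20 and 6 to 18 reads in the DMSO libraries. In the haloperidol libraries they had 4 to 8, 2 to 3 and 0 to 2. Flt3, a receptor gene of lymphoid-primed progenitors, did not fall. It was at 103 ± 2.36 and 116 ± 5.21 FPKM (adjusted p = 0.0484, and 0.0729 to 0.154 with any 1 library left out).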
